A study of Mus musculus with 2 samples.

How the data were processed

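The deposited files held UMI counts per gene and barcode as whole numbers. Per the labels' protocols, cells were sorted directly into the master mix and libraries were made with 10x Genomics 3' v3.1 chemistry. Per the file headers and the labels, reads were counted with Cell Ranger 7.0.0 against mm10. Whether intronic reads were counted, which release of gene models was used and how barcodes were called as cells were not given in the sources used here. The smallest deposited barcode held 501 UMIs in RORgt_high and 504 in RORgt_LTi, so barcodes below these totals had been left out before deposit, and whether empty droplets remained was not tested. The matrices held 32286 features, among them an added RORgt-EGFP feature, and 78 features that shared a symbol were kept apart by their identifier. Of the identifiers, 32235 (99.8%) matched GENCODE vM21, from which the mm10 coordinates were taken. Reads of the knocked-in reporter transcript can map to Rorc or to RORgt-EGFP, and the near-identical pairs Hba-a1 and Hba-a2 and Hbb-bs and Hbb-bt can share reads, so the values of these genes are less certain than others.

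The files were read with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, clustered with scanpy 1.11.5, scikit-learn 1.9.0 and igraph 0.11.9, and drawn with matplotlib 3.10.9. Barcodes with under 500 genes (548 in RORgt_high, 27 in RORgt_LTi) or over 10% mitochondrial UMIs (1121 and 68) were removed, which took 28.7% and 5.77% of barcodes. Scrublet was run per library on the 3669 and 1306 passing barcodes and called 1 doublet in RORgt_high (0.0273%) and 19 in RORgt_LTi (1.45%), which were removed. At the usual rate of 0.8% per 1000 cells the call in RORgt_high was too low, so an added run removed the highest doublet scores, 151 cells (4.12%) and 14 cells (1.07%). Median mitochondrial UMIs of kept cells were 2.56% in RORgt_high and 2.07% in RORgt_LTi. Kept cells held 42731219 UMIs in RORgt_high, where 1 UMI stood for 0.0234 CPM, and 10670689 in RORgt_LTi, where it stood for 0.0937 CPM.

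For clustering, both libraries were joined, scaled to 10000 UMIs per cell and log-transformed. Cell cycle, mitochondrial, ribosomal, hemoglobin, sex-linked and antigen receptor segment genes were left out, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.8 were used without correction between libraries, since library and gate were the same thing. Clusters were named from 16 fixed marker classes. A class score was the mean over its markers of log2 of the cluster's CPM plus 10 over the mean of clusters plus 10, for markers that reached 20 CPM in some cluster. A cluster took the class with the highest score if at least 3 markers were detected in 10% of its cells and the score was at least 1. It was called LTi-like if its LTi score was above 0 with 3 markers detected, no class outside the LTi, ILC progenitor and T-cell classes scored 1 or more, and its top 10 genes held no more markers of another class. Clusters with a median under 1/3 of the library median and no own marker in the top 10 stayed unnamed. The score threshold was set after the data were seen, and the marker classes before.

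Comparisons between groups used counts summed over the cells of a library, scaled to the library's total. CPM had exact Poisson 95% intervals, ratios had exact conditional intervals and shares had exact binomial intervals. Genes needed at least 50 UMIs over both libraries. A fold against 0 UMIs was given as at least the value with 3 counts in the empty library. No p-values over cells were made, since cells of a library are not replicates. The named genes were the 12 per direction and comparison ranked by the interval end nearest 1 among genes found in 5% of cells of the library with more. The 4 gate genes, the reporter, sex-linked, hemoglobin, mitochondrial, ribosomal and receptor segment genes and unnamed gene models were left out of this ranking, since the gates and preparation act on them directly or they have no known role. Each of 32 gene lists was summed up by its called members, its median log2 ratio and the percentile of that median among 10000 random lists matched over 20 expression bins. Shares of cells with a UMI were made after each cell was thinned to 1500 UMIs without replacement, the lower of the libraries' 20th percentiles (1667.4 UMIs in RORgt_high, 5593 in RORgt_LTi) taken down to a multiple of 500. Rorc strata used thinned cells with at least 2 or with 0 Rorc UMIs, and cycling cells had at least 2 UMIs of 5 genes.

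The comparison step was tested on simulated data, sums of UMIs drawn from the mean of each gene over both libraries at their totals, with 50 genes per simulated fold. The draws held no variation between libraries, cells or preparations, so the shares called below cover counting error only. They are not the error rate of the real comparison. Over all cells (13251 genes) 36% of 1.5-fold genes, 98% of 2-fold genes and 100% of 4-fold and 0.25-fold genes were called, and 0.858% of unchanged genes (112 of 13051). In LTi-like cells (11522 genes) the calls were 22%, 98%, 100% and 100%, and 0.751% of unchanged genes (85 of 11322).

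Alternatives chosen before the data were examined were median-of-ratios scaling, totals without mitochondrial, ribosomal and hemoglobin genes, the mean over cells of each cell's share, thinned cells, no filter on low counts, at least 1000 genes and at most 5% mitochondrial UMIs, all deposited barcodes, called doublets kept, Leiden resolution 0.4 and 1.2, cell cycle genes kept and each library clustered on its own. Alternatives added later left out the erythroid, macrophage, hepatoblast and mast clusters, left out the shallow clusters, removed the highest doublet scores, left out histone genes and counted the deep unnamed clusters as LTi-like. No pseudotime or RNA velocity was made, since with 1 library per gate an ordering of cells could not be told from the library, and the files held no spliced and unspliced counts.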

Results

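The series held single-cell RNA counts from sorted cells of mouse fetal liver at embryonic day 14.5, taken from RORgt-EGFP reporter mice on the C57BL/6 strain. There were 2 groups with 1 library each. RORgt_high held lineage-negative cells with integrin α4β7 and high GFP, and RORgt_LTi held lineage-negative cells with c-kit and high GFP. Up to 10000 cells were sorted per library. The deposited matrix of RORgt_high held 5147 barcodes and 45839321 UMIs, of which 3668 cells with a median of 11411 UMIs and 3566 genes were kept. RORgt_LTi held 1386 barcodes and 10950536 UMIs, of which 1287 cells with a median of 7440 UMIs and 2716 genes were kept. The stated aim of the series was to follow how progenitors of lymphoid tissue inducer (LTi) cells, the innate lymphoid cells that start lymph nodes and Peyer's patches, mature as the level of RORγt goes up. The labels gave high GFP for both gates, so the groups differed by label in the second surface protein and not in the stated level of GFP.

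Unless another pair is named, ratios were RORgt_LTi over RORgt_high on counts per gene scaled to library total (CPM). A gene was called higher or lower in RORgt_LTi when its ratio was at least 1.5 or at most 1/1.5 and its 95% interval left out 1. Intervals covered counting error only, and with 1 library per group no test and no check between replicates was possible. Gene lists and the thresholds on ratios were set before the data were examined, while the score threshold that named the cell clusters was set after. List medians were log2 ratios, and each list's percentile was its place among 10000 random lists matched for expression.

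The first comparison checked the labels with the genes behind the gates. Rorc (ENSMUSG00000028150, chromosome 3, 94372794 to 94398276, plus strand), which encodes the nuclear receptor RORγt that LTi cells need, was at 1624 CPM (1612 to 1636) in RORgt_high and 950.0 CPM (932 to 969) in RORgt_LTi. Its ratio was 0.585 (0.573 to 0.597). The RORgt-EGFP reporter feature was likewise lower in RORgt_LTi, at 40.1 CPM (36.4 to 44.1) against 81.8 (79.1 to 84.5). Kit (ENSMUSG00000005672, chromosome 5, 75574916 to 75656722, plus strand), the stem cell factor receptor of the RORgt_LTi gate, was at 116 CPM (110 to 123) in RORgt_LTi and 108 (105 to 111) in RORgt_high, a ratio of 1.08 and so neither higher nor lower. Of the chains of α4β7, the integrin that guides cells to the gut, Itgb7 (ENSMUSG00000001281, chromosome 15, 102215995 to 102231944, minus strand) was lower in RORgt_LTi at 103 against 183 CPM (ratio 0.562, 0.527 to 0.599). Itga4 (ENSMUSG00000027009, chromosome 2, 79255426 to 79333123, plus strand) was at 482 against 685 CPM, a ratio of 0.703 that did not reach the threshold. Il7r (ENSMUSG00000003882, chromosome 15, 9505788 to 9530176, minus strand), the interleukin-7 receptor alpha chain of lymphoid progenitors, was at 686 against 565 CPM (ratio 1.22).

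After thinning every cell to 1500 UMIs, which left 3025 of 3668 and 1257 of 1287 cells, a Rorc UMI was present in 84.3% (83.0 to 85.6) of RORgt_high and 71.0% (68.4 to 73.5) of RORgt_LTi cells. At the deposited depth and over all kept cells the shares were 91.7% and 94.7%, the opposite order. Thinning also left out cells, mostly of RORgt_high, so depth alone need not account for this turn. Within LTi-like cells the share was higher in RORgt_high at both depths, though at the deposited depth the intervals overlapped. Among erythroid-like cells of RORgt_high, which should lack Rorc, 12.9% (12 of 93) had a Rorc UMI after thinning and 34.2% at their deposited median of 4546.5 UMIs. Among mast-like cells of RORgt_LTi the share was 0 of 16 after thinning and 5.88% (1 of 17) at a median of 9544 UMIs. Il22 was present in 47.7% of thinned RORgt_LTi cells and 2.48% of thinned RORgt_high cells (65.5% and 8.83% at deposited depth), and in 0 of 93 thinned erythroid-like cells of RORgt_high and 1 of 16 thinned mast-like cells of RORgt_LTi (6.25%, 0.158 to 30.2).

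**Figure D1:**
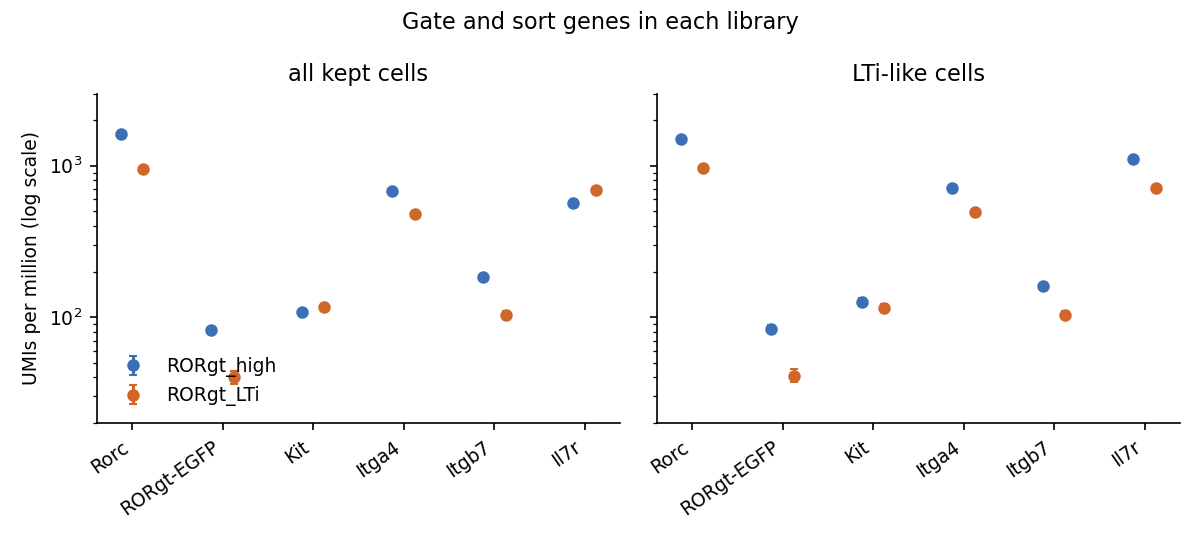
Level of 6 gate genes in CPM on a log axis for RORgt_high and RORgt_LTi, in all kept cells and in LTi-like cells; points are summed counts and bars are 95% counting intervals. Rorc was lower in RORgt_LTi in both panels (ratio 0.585 and 0.637), while Kit was close to equal (1.08 and 0.910).

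The second comparison asked which cell types each gate held. Cells named LTi-like from fixed markers made up 94.9% (93.5 to 96.0, 1221 of 1287) of RORgt_LTi, the c-kit gate, and 29.3% (27.8 to 30.8, 1075 of 3668) of RORgt_high, the α4β7 gate. RORgt_high also held dendritic-like cells (11.8%, 10.8 to 12.9, against 0.0777%), ILC1 or NK-like cells (4.47%, 3.83 to 5.19, against 0.233%), erythroid-like cells (3.27%, 2.72 to 3.90, against 0 of 1287, which allowed up to 0.286%) and macrophage-like cells (0.736% against 0.0777%). The dendritic-like cluster scored 1.102, just above the threshold of 1, with 0 of its class's markers in its top 10 genes. Thinned dendritic-like cells with at least 2 Rorc UMIs numbered 299 and those with 0 numbered 46. The same counts were 98 and 19 in ILC1 or NK-like cells, and 2 and 81 in erythroid-like cells. At Leiden resolution 0.4 no cluster took the dendritic, ILC1 or NK, or macrophage name. With RORgt_high clustered on its own, 296 cells were ILC1 or NK-like. Mast or basophil-like cells were found only in RORgt_LTi (1.32%, 0.771 to 2.11, against 0 of 3668, which allowed up to 0.1005%). Hepatoblast-like cells made up 0.627% of RORgt_high (23 cells, with 1411 Alb UMIs). They numbered 50 at Leiden resolution 0.4, 51 with cell cycle genes kept, 94 with doublets kept and 21 with RORgt_high clustered on its own. The 13 cells of RORgt_LTi in the same cluster (1.01%) held 0 Alb and 0 Rorc UMIs but 121 of the library's 130 UMIs of Col1a1 and 172 of its 173 of Col3a1, collagen genes of stromal cells, so their own markers went against the name. Cells in clusters that no marker class named made up 49.8% of RORgt_high (1825 cells) and 2.41% of RORgt_LTi (31 cells). Of the unnamed, 3 deep clusters (4, 5 and 6) held 8.92%, 7.85% and 7.47% of RORgt_high and 0.389%, 0.699% and 0.155% of RORgt_LTi. The other 2, clusters 1 and 12, were shallow and held 22.8% and 2.75% of RORgt_high and 0.777% and 0.389% of RORgt_LTi.

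The LTi-like class was in clusters 2 and 7 for RORgt_high (827 and 243 cells) and in clusters 0, 8 and 10 for RORgt_LTi (893, 174 and 137 cells), and a cluster held mostly by 1 library may be that library and not a type. Clusters 2 and 7 scored higher on ILC progenitor markers (0.473 and 0.399) than on LTi markers (0.128 and 0.277), whereas clusters 0 and 10 scored highest on LTi markers (0.785 and 0.480) and cluster 8 scored 0.235 on them against 0.262 on T-cell markers, so ratios within the class compare unlike parts of it. When each library was clustered on its own the LTi-like share was 26.0% and 71.6%, and when the deep unnamed clusters were counted as LTi-like the share of RORgt_high became 53.5%.

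**Figure D2:**
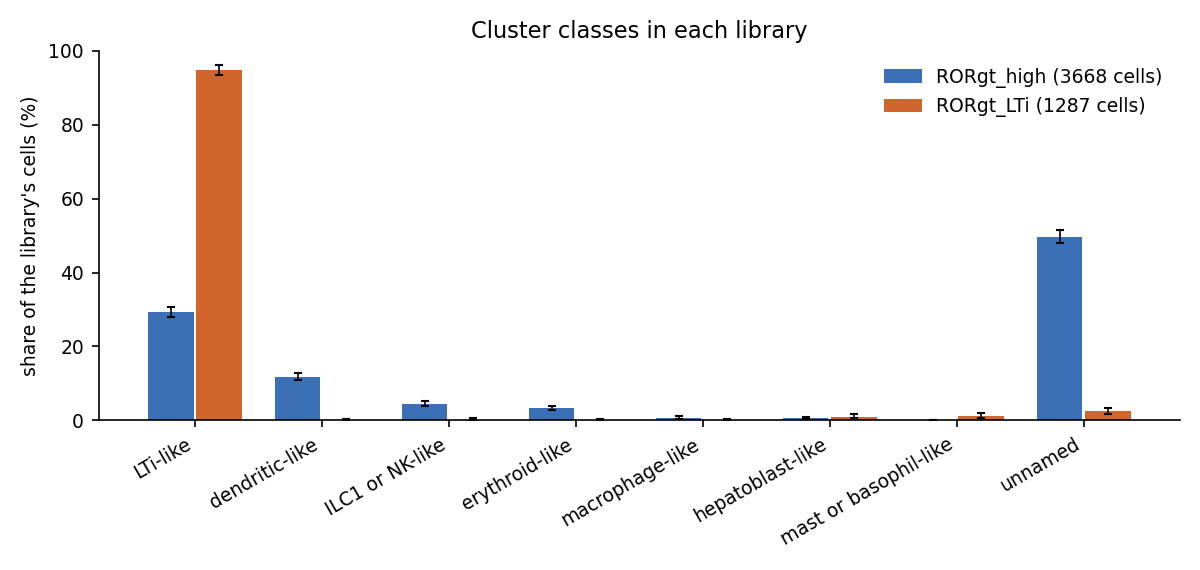
Share of cells in percent per cell class in RORgt_high (α4β7 gate) and RORgt_LTi (c-kit gate), with 95% intervals for counting error. LTi-like cells filled 94.9% of RORgt_LTi and 29.3% of RORgt_high, where 49.8% of cells stayed unnamed.

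**Figure D3:**
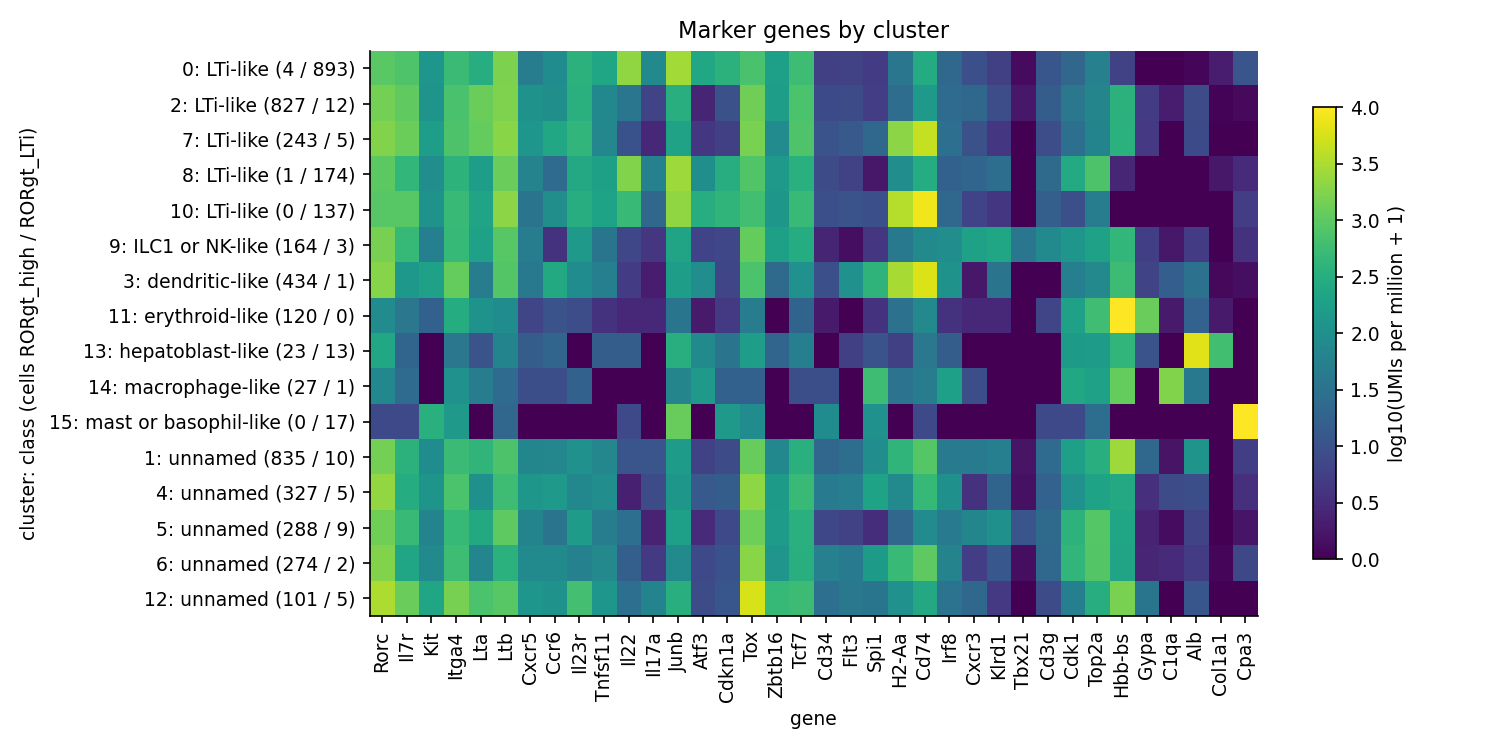
Heat map of log10 (CPM + 1) for 36 marker genes (columns) in 16 clusters (lines, with cells per library). A reader should see that the LTi-like clusters are each held by 1 library, such as cluster 0 with 893 cells of RORgt_LTi and 4 of RORgt_high.

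The third comparison asked which genes differed between the gates over all kept cells. Il22 (ENSMUSG00000074695, chromosome 10, 118204942 to 118210047, plus strand), which encodes interleukin-22, a cytokine of mature LTi cells and ILC3s, was higher in RORgt_LTi at 1790 against 22.1 CPM, a ratio of 80.9 (75.8 to 86.5). Il17a, another cytokine of RORγt-dependent cells, was higher at 64.0 against 4.54 CPM (14.1), and Il17f by 2.81. Lta (ENSMUSG00000024402, chromosome 17, 35203165 to 35205351, minus strand), which encodes lymphotoxin alpha that LTi cells use to start lymphoid organs, was lower in RORgt_LTi. It was at 254 against 505 CPM (0.502, 0.483 to 0.523). Tnfsf11, which encodes the cytokine RANKL, was higher by 3.15 (2.97 to 3.33), and Ltb, the partner of Lta, by 1.504 (1.48 to 1.53), a call that ended at 1.482 with totals that left out mitochondrial, ribosomal and hemoglobin genes. Cxcr5, the receptor for CXCL13 that draws LTi cells to organ anlagen, was lower at 0.565.

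Among the genes ranked highest by the interval end nearest 1, Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727, plus strand), which encodes the cell cycle inhibitor p21, was at 349 against 7.98 CPM (43.7, 39.1 to 49.0) and Nr4a3, an early activation nuclear receptor, at 58.6 against 0.726 CPM (80.7, 56.3 to 120). Vegfa, an angiogenic factor, was at 38.1 against 0.515 CPM (74.1, 48.3 to 120). Cxcl2, a neutrophil chemokine, was at 273 against 9.48 (28.8, 25.9 to 32.0), and Socs3, a feedback inhibitor of cytokine signals, at 128 against 5.71 (22.5, 19.6 to 25.9). Ptgs2, the inducible cyclooxygenase, was higher by 23.7 (18.2 to 31.4), Adm by 49.2 (22.9 to 126), Plagl1 by 61.7 (34.5 to 122) and Lsmem1 by 127 (42.1 to 626, from 3 UMIs in RORgt_high). Cma1, a mast cell protease, was at 581 CPM and absent from RORgt_high (at least 8269-fold), and Hdc, the histamine-making enzyme of mast cells and basophils, was at 74.1 against 3.25 CPM (22.8, 19.0 to 27.5).

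The genes ranked lowest in RORgt_LTi by the same rule included those of red cells and hepatoblasts. Gypa, Snca, Slc4a1 and Ermap of erythroid cells had no UMI in RORgt_LTi and were lower by at least 121-fold, 110-fold, 102-fold and 62.1-fold. Alb (ENSMUSG00000029368, chromosome 5, 90460897 to 90476602, plus strand), which encodes albumin, was at 0.0937 against 46.7 CPM (0.00201, 0.0000508 to 0.0112, from 1 UMI), with Ttr at 0.187 against 26.5 CPM (0.00707, 0.000855 to 0.0256, from 2 UMIs) and Afp at 1.78 against 76.1 CPM (0.0234, 0.0141 to 0.0366). Cd24a (0.00542, 0.000656 to 0.0196) and Rhd (0.00589, 0.000713 to 0.0213), each from 2 UMIs, Lmo2 (0.00944, 0.00194 to 0.0276, from 3 UMIs) and Bex6 (0.0070, 0.0019 to 0.0179) had ratios of the same order. Itgam, the myeloid integrin, was at 2.25 against 103 CPM (0.0219, 0.0140 to 0.0326).

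By list, LTi identity and effector genes had 8 higher and 6 lower of 19 (median 0.33, percentile 99.1), with Il23r at 1.74, Tmem176a at 2.02 and Tmem176b at 2.24, and Ccr6 at 0.634 and Maf at 0.495. With median-of-ratios scaling, which moved the median of all genes from -0.18 by 0.11, the split of this list was 9 and 4. E proteins and lymphoid transcription factors had 13 higher and 5 lower of 26 (0.55, percentile 100). Among them were the NF-κB genes Relb (5.44), Rel (4.29) and Nfkb2 (3.31), with Klf2 at 3.69, Bach2 at 2.72 and Ikzf1 at 0.454. Immediate early and stress genes, which cells switch on within minutes of a stimulus or of handling, had 17 higher and 0 lower of 22 (1.58, percentile 100). Junb (ENSMUSG00000052837, chromosome 8, 84974484 to 84978718, minus strand) was at 2601 against 192 CPM (13.5, 13.2 to 13.9) and Atf3, which had the largest ratio of the list, at 209 against 13.6 CPM (15.3), with Hspa1a at 13.01 (9.22 to 18.7), Nr4a1 at 8.93 and Fos at 6.11. ILC progenitor factors had 2 higher and 6 lower of 15 (-0.21, percentile 13.4), with Rora at 3.85 and Id2, the inhibitor that sets innate lymphoid fate, at 0.443. Lymphotoxin and TNF family genes had 5 higher and 4 lower of 13 (-0.17, percentile 35.9), chemokine and homing genes 2 higher and 8 lower of 19 (-0.43, percentile 0.565), and cytokine receptors 6 higher and 4 lower of 23 (0.11, percentile 92.9). The LTi identity list shared 3 genes with each of these last 3 lists, such as Lta, Cxcr5 and Il23r.

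The cell cycle lists were lower in RORgt_LTi, with 1 higher and 23 lower of 42 S-phase genes (-0.60, percentile 0; 1 and 13 with median-of-ratios scaling) and 0 higher and 34 lower of 52 G2/M genes (-0.78, percentile 0). Multipotent progenitor genes had 4 higher and 6 lower of 16 (-0.51, percentile 7.69), with the stem cell marker Cd34 at 0.361 and the cytokine receptor Flt3 at 0.173. Interferon-response genes had 3 higher and 10 lower of 16 (-0.82, percentile 0.07) and apoptosis genes 7 higher and 5 lower of 18 (0.19, percentile 95.9). There were 3 higher and 1 lower among 17 glycolysis genes (0.07, percentile 80.6), oxidative phosphorylation genes 0 and 2 of 26 (-0.01, percentile 50.5, or 0 and 1 with median-of-ratios scaling), and cholesterol genes 1 and 1 of 17 (-0.16, percentile 62.6). Median-of-ratios scaling made the cholesterol split 4 and 1, and totals without mitochondrial, ribosomal and hemoglobin genes made it 1 and 2. Mitochondrially encoded genes, a mark of RNA quality, had 0 higher and 1 lower of 13 (-0.36, percentile 1.72), at 21050 against 26250 CPM in sum, beside all of these lists.

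Of the lists for other lymphoid types, ILC2 genes had 3 higher and 4 lower of 10 (-0.41, percentile 16.6). ILC1 and NK genes had 2 and 8 of 12 (-0.97, percentile 0.17, with a median of 0.38 in thinned cells). T-cell genes had 3 and 1 of 9 (0.13, percentile 83.6). B-progenitor genes had 2 and 3 of 5 (-1.17, percentile 3.21; split 1 and 3 without mitochondrial, ribosomal and hemoglobin genes) and MHC class II genes 2 and 6 of 13 (-0.45, percentile 5.04). Several list medians are also given with absent genes set to the 3-count floor. Hemoglobin genes had 0 higher and 6 lower of 6 (-13.15, floor -12.66, 0.375 against 7242 CPM), erythroid genes 0 and 12 of 13 (-8.54, floor -5.96) and hepatoblast genes 0 and 8 of 9 (-5.38, floor -4.75), each at percentile 0. Macrophage genes had 2 higher and 8 lower of 12 (-2.69, floor -2.51, percentile 0). Neutrophil and monocyte genes had 3 and 5 of 9 (-1.84, percentile 0, with a median of 0.85 in thinned cells). Megakaryocyte genes had 1 and 4 of 6 (-2.29, floor -1.74, percentile 0.38, with a median of 0.0021 in thinned cells). Dendritic genes had 3 and 3 of 6 (-0.38, floor -0.38, percentile 13.3). Thinning leaves fewer UMIs per gene, so fewer members of a list may pass the UMI filter. Whether the thinned medians show another direction or rest on other members was not tested. Mast cell genes had 7 higher and 0 lower of 7 (9.04, floor 7.20, percentile 100), stromal genes 7 and 1 of 8 (3.56, percentile 100), endothelial genes 1 and 3 of 6 (-0.49, percentile 42.1) and sex-linked genes 3 and 0 of 6 (0.49, percentile 97.3). Fetal liver itself makes the erythroid, hepatoblast, macrophage and megakaryocyte RNAs, and 4 hemoglobin genes were in both the hemoglobin and the erythroid list. The dendritic list shared Flt3, Irf8, Batf3 and Bst2 with other lists, and the ILC2 list shared Gata3, Rora, Bcl11b, Il17rb and Il1rl1.

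The fourth comparison kept to LTi-like cells, in clusters 2 and 7 for RORgt_high and 0, 8 and 10 for RORgt_LTi. Il22 was again higher in RORgt_LTi at 1874 against 43.9 CPM (42.7, 39.4 to 46.4), as were Il17a (13.4, 10.4 to 17.4) and Tnfsf11 (2.97, 2.76 to 3.21). Lta was lower at 264 against 1255 CPM (0.211, 0.202 to 0.219), a wider gap than over all cells, and Ltb was close to equal at 0.907. Cxcr5 was lower at 0.432 (0.390 to 0.478), Ccr6, the CCL20 receptor of LTi cells, at 0.575, and Cxcr6 at 0.396 (0.365 to 0.429). Bcl2, which keeps lymphocytes alive downstream of interleukin-7, was lower at 0.319 (0.307 to 0.332), and Lgals3 (ENSMUSG00000050335, chromosome 14, 47367751 to 47386160, plus strand), which encodes galectin-3, was at 10.7 against 330 CPM (0.0324, 0.0265 to 0.0392).

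Rorc itself was at 961 against 1507 CPM in LTi-like cells (0.637, 0.622 to 0.653), with EGFP at 41.0 against 83.2, Kit at 115 against 127 (0.910) and Itga4 at 493 against 717 (0.688). Itgb7 was at 104 against 161 (0.644) and Il7r at 710.3 against 1103 (0.644). Median-of-ratios scaling moved the median of all genes in these cells from -0.20 by 0.19 and brought Rorc to 0.725, which ended its lower call. LTi markers named this class, so their levels in it were not an independent finding.

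Ranked by the interval end nearest 1, the genes highest in LTi-like cells of RORgt_LTi included the stress factor Atf3 (ENSMUSG00000026628, chromosome 1, 191170296 to 191218039, minus strand) at 211 against 2.03 CPM (104, 71.8 to 157), Nr4a3 (69.8, 39.7 to 136), Cdkn1a at 360 against 8.42 CPM (42.8, 35.6 to 51.9) and Cxcl2 at 274 against 9.65 CPM (28.4, 23.9 to 34.1). Plaur, the urokinase receptor, was higher by 48.4 (20.4 to 151) and Ankrd33b by 36.9 (19.8 to 77.9). From 3 UMIs or fewer in RORgt_high came Vegfa (39.9 against 0.218 CPM, 183.5, 62.4 to 894), Bmp2 (20.1 against 0.218 CPM, 92.4, 31.2 to 452), Plagl1 (199, 35.1 to 7906) and Adm (109.6, 19.1 to 4380). Cma1 was at 11.6 CPM against 0 (at least 53.2-fold), from 118 of the 6195 Cma1 UMIs of RORgt_LTi. Mast-like cells were found only in that library, and whether free RNA from them gave these UMIs was not tested.

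On the lower side stood Slfn2, a factor of lymphocyte quiescence, at 45.1 against 268 CPM (0.168, 0.152 to 0.185), Amph at 13.5 against 82.1 CPM (0.165, 0.137 to 0.197) and Cdca7, a replication-linked chromatin gene, at 11.3 against 68.0 CPM (0.166, 0.136 to 0.202). Wdfy4 (0.102), Tifab (0.109), Vmn2r26 (0.0939, 0.0538 to 0.153) and Flrt2 (0.0751, 0.0238 to 0.182) were lower too. The metallothionein gene Mt1 was lower at 0.127 (0.0815 to 0.190) and its neighbor Mt2 by at least 16.0-fold. Alb (0.0130, 0.000326 to 0.0741, from 1 UMI) and Gypa, which had no UMI in RORgt_LTi (at least 13.55-fold), stood among the lowest here too.

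By list, LTi identity genes had 6 higher and 4 lower of 19 (-0.06, percentile 44.0) and lymphotoxin and TNF family genes 4 and 4 of 13 (-0.03, percentile 70.2). E proteins and lymphoid transcription factors had 12 higher and 2 lower of 25 (0.38, percentile 100, or 12 and 1 with median-of-ratios scaling), with Rel at 5.92 (5.47 to 6.42), Relb at 4.47 (4.08 to 4.90), Klf2 at 3.84 and Ikzf1 at 0.423. The same cells had 17 higher and 0 lower of 21 immediate early genes (1.37, percentile 100), with Fosl2 at 11.1, Junb at 8.71, Nr4a1 at 5.71 and Fos at 4.15. Hspa8 (1.05), Hsp90aa1 (0.976) and Egr1 (0.899) of that list were neither higher nor lower. Chemokine and homing genes had 3 higher and 7 lower of 18 (-0.35, percentile 2.61), with Cxcr4, the CXCL12 receptor that holds cells in liver and marrow, at 28.8 against 1.16 CPM (24.8). ILC progenitor factors had 2 higher and 4 lower of 14 (-0.26, percentile 7.75; 2 and 2 with median-of-ratios scaling), with Nfil3 at 5.03 (4.56 to 5.57), Rora at 2.60 (2.53 to 2.67), Id2 at 0.556 and Tox at 0.506. Multipotent progenitor genes had 5 and 5 of 12 (-0.17, percentile 64.5; 5 and 3 with that scaling) and cytokine receptors 4 and 4 of 21 (-0.13, percentile 47.3; 5 and 2).

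G2/M genes turned round against all cells, with 37 higher and 1 lower of 52 (0.83, percentile 100) and Top2a, the mitotic topoisomerase, at 3.29, while S-phase genes had 3 higher and 15 lower of 42 (-0.39, percentile 0.6). The G2/M direction rested on leaving the deep unnamed clusters out of the class, since counting them in gave 0 higher and 41 lower (median -0.89). The 37 higher became 11 in thinned cells or at Leiden resolution 0.4, 18 as a mean over cells and 22 with doublets kept or without histone genes, and the S-phase median was 0.12 at Leiden resolution 1.2. Apoptosis genes had 8 higher and 3 lower of 18 (0.40, percentile 99.9), with the death receptor Fas at 11.4 and Bcl2l1 at 0.425. Interferon genes had 6 and 4 of 13 (0.01, percentile 86.7), glycolysis genes 4 and 1 of 17 (0.02, percentile 74.5; 4 and 0 with median-of-ratios scaling), oxidative phosphorylation genes 0 and 2 of 26 (-0.07, percentile 30.1; 1 and 1) and cholesterol genes 3 and 3 of 17 (0.01, percentile 93.3; 3 and 1).

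Of the other lymphoid lists, ILC1 and NK genes had 3 higher and 1 lower of 9 (0.52, percentile 99.05, or 5 and 1 with median-of-ratios scaling), with Ifng at 29.98 (13.4 to 83.2), though the median was -0.92 at Leiden resolution 0.4 and -0.31 with the deep unnamed clusters counted in. ILC2 genes had 2 and 0 of 7 (-0.23, percentile 42.7), T-cell genes 1 and 1 of 7 (0.12, percentile 87.6; 1 and 0 with median-of-ratios scaling), MHC class II genes 1 and 0 of 11 (0.11, percentile 89.6; 4 and 0 with that scaling) and B-progenitor genes 1 and 0 of 2 (0.31). Red cell RNA stayed low in RORgt_LTi inside this class, with hemoglobin genes 0 higher and 4 lower of 4 (-10.34, floor -9.81, 0.393 against 790.4 CPM). Erythroid genes had 1 and 6 of 8 (-7.93, floor -6.35, percentile 0, with Car2 higher at 3.11). Hepatoblast genes had 1 and 3 of 5 (-2.44, floor -2.44, percentile 0). Their median was 0.75 in thinned cells, where fewer members may pass the UMI filter. Mast cell genes had 3 and 0 of 3 (4.96, floor 4.96, percentile 100), but only RORgt_LTi held mast-like cells, and free RNA from these was not tested. Neutrophil and monocyte genes had 2 and 0 of 2 (2.94), macrophage genes 2 and 0 of 2 (2.24) and megakaryocyte genes 2 and 0 of 2 (0.77). Dendritic genes had 2 and 1 of 5 (0.33, percentile 92.4; 2 and 0 with median-of-ratios scaling), endothelial genes 1 and 0 of 4 (-0.09, percentile 64.9; 1 and 1 without mitochondrial, ribosomal and hemoglobin genes), stromal genes 1 and 1 of 3 (0.13, percentile 77.6), sex-linked genes 2 and 0 of 6 (0.45, percentile 97.4) and mitochondrially encoded genes 0 and 2 of 13 (-0.40, percentile 0.305, or 0 and 1 with median-of-ratios scaling).

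**Figure D4:**
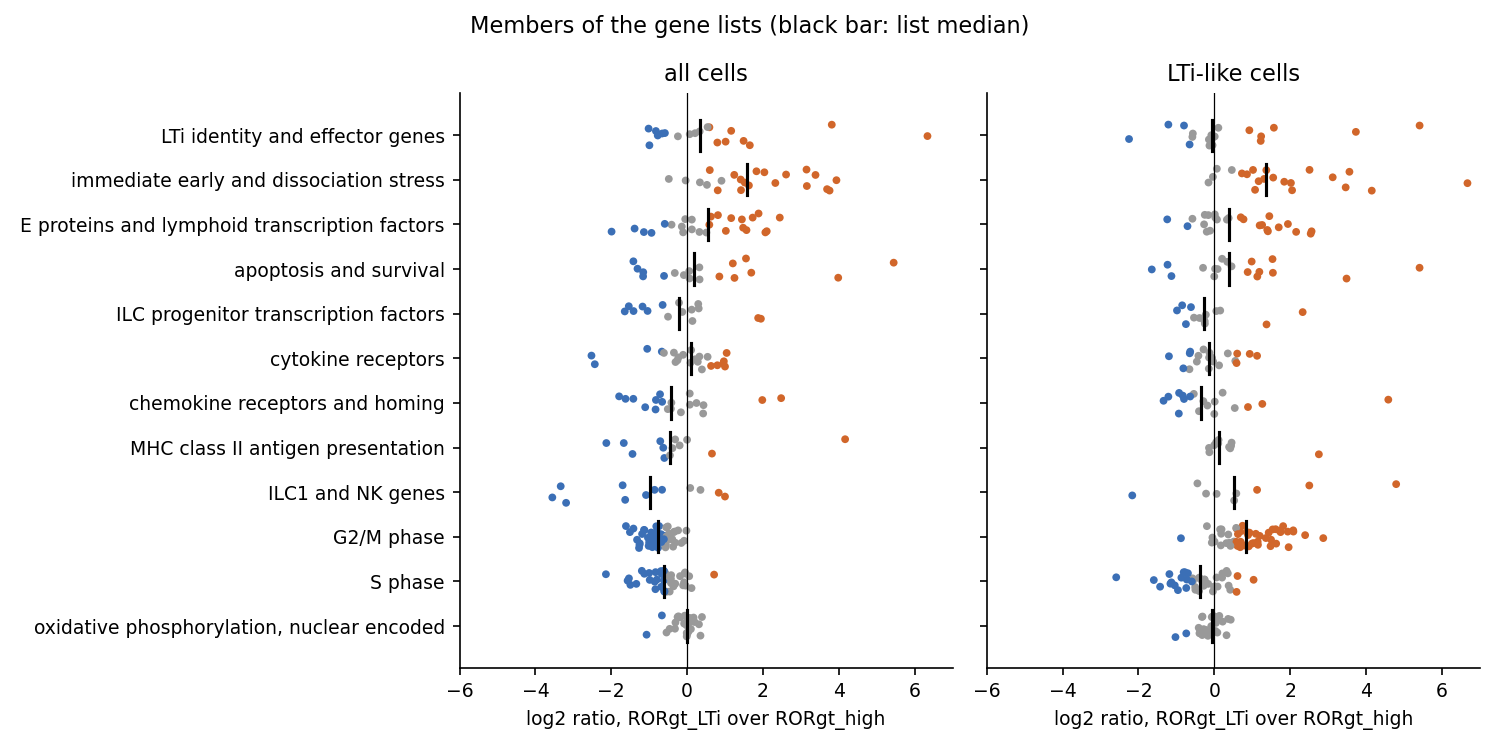
Log2 ratio of RORgt_LTi over RORgt_high for each measured member of 12 gene lists, over all cells and over LTi-like cells; each point is a gene, orange higher, blue lower and grey neither, with black bars at list medians. Immediate early genes lay to the higher side in both panels (median 1.58 and 1.37), while G2/M genes changed side (-0.78 and 0.83).

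The fifth comparison asked, within each library, how genes went with the level of Rorc, setting thinned cells with at least 2 Rorc UMIs against those with 0. In RORgt_high (1950 against 474 cells) 10 of 16 LTi identity genes were higher in Rorc-rich cells and 1 was lower (median 0.73, percentile 100). Cd4, carried by many LTi cells, had a ratio of 2.44 (1.66 to 3.70) and Ccr6 of 2.08 (1.54 to 2.86). Cxcr5 had a ratio of 1.98 (1.36 to 2.98), Il23r of 1.93 (1.54 to 2.44) and the reporter of 2.54 (1.78 to 3.72). Lta (1.09) and Ltb (1.247) were neither, and Il22 was lower at 0.540 (0.324 to 0.926). ILC progenitor factors were higher too, with 8 higher and 1 lower of 14 (0.63), among them Tox at 1.82 and Tcf7 at 1.64. So were chemokine and homing genes, with 8 and 0 of 16 (0.66), and cytokine receptors, with 8 and 0 of 18 (0.57). Hbb-bs had a ratio of 0.0278 in the same cells, and 17.1% of Rorc-free but 0.103% of Rorc-rich cells were erythroid-like. Cell cycle genes leaned to the Rorc-free side, with 0 higher and 10 lower of 41 S-phase genes (-0.34) and 0 and 4 of 48 G2/M genes (-0.28).

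In RORgt_LTi (497 against 364 cells) 1 of 16 LTi identity genes was higher in Rorc-rich cells, the ligand-activated factor Ahr (2.20, 1.43 to 3.48), and 1 was lower, Il17f (0.663, 0.453 to 0.967), with a median of -0.02 (percentile 40.04). Cd69 (2.71), Klf2 (2.28) and Ccl5 (2.22) were higher in those cells. ILC progenitor factors had 0 higher and 0 lower of 12 (0.14) and G2/M genes 5 and 0 of 30 (0.29), and mast-like cells made up 4.40% of the Rorc-free cells. Cells with exactly 1 Rorc UMI, next to both strata, numbered 601 in RORgt_high and 396 in RORgt_LTi. Within LTi-like cells alone the RORgt_high result was 0 higher and 0 lower of 14 (0.35, 666 against 134 cells) and the RORgt_LTi result 1 higher and 3 lower of 16 (-0.13, 488 against 329 cells). At deposited depth 16 and 17 LTi genes were higher in the libraries. The count of 10 in RORgt_high thus held neither at deposited depth nor within LTi-like cells.

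**Figure D5:**
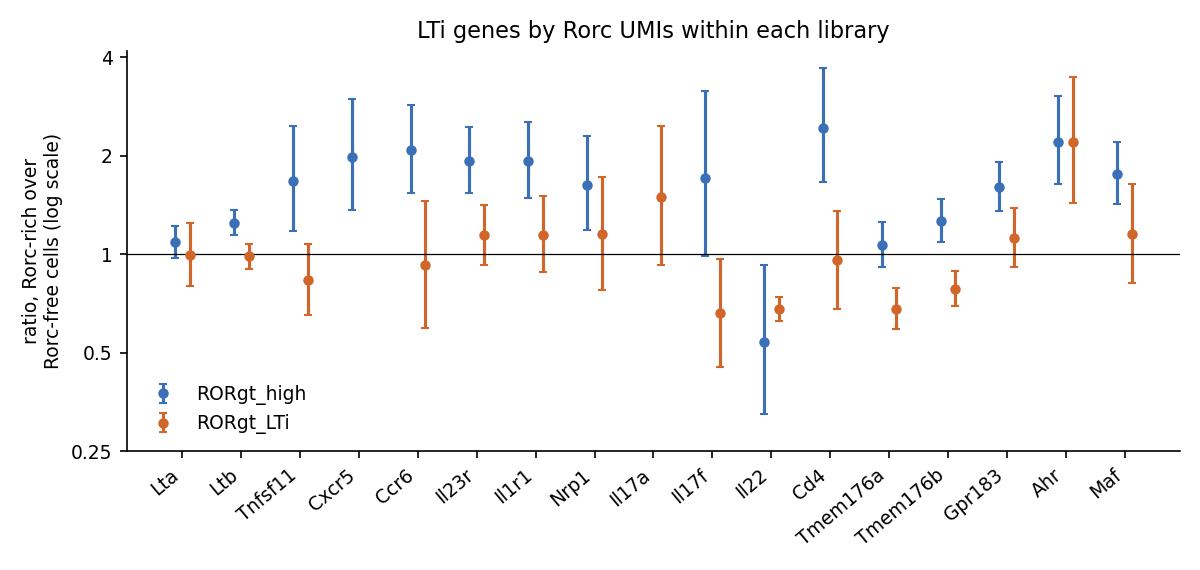
Ratio of Rorc-rich over Rorc-free cells on a log axis for LTi identity genes in each library, with 95% intervals; genes with too few counts are not drawn. Most points of RORgt_high lay above 1 (Cd4 at 2.44, Ccr6 at 2.08). Those of RORgt_LTi scattered around 1, which strata mixed by counting can also give.

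The last comparison counted cycling cells, those with at least 2 UMIs of Mki67, Top2a, Cdk1, Ccnb2 and Birc5, which dividing cells express in G2 and mitosis. Over thinned cells the share was 30.7% (29.1 to 32.4, 929 of 3025) in RORgt_high and 16.1% (14.1 to 18.2, 202 of 1257) in RORgt_LTi, and over all cells Cdk1 had a ratio of 0.459 and Top2a of 0.622. Within LTi-like cells it was 8.95% (7.29 to 10.9) and 15.3% (13.4 to 17.5), so the order was the reverse. That reversal rested on the class, which left out the deep unnamed clusters of RORgt_high, since counting these in gave 31.7% and 16.1%. Without thinning the shares were 53.2% and 27.7% over all cells and 45.1% and 27.0% in LTi-like cells. Asking for at least 4 UMIs gave 14.9% and 8.12%, asking for 1 gave 47.3% and 24.3%, and no class in these libraries is known to lack these genes as a background.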

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

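The tests of hemoglobin proportions and of Rorc among cells of low UMI count were written down before they were run, and all other tests in this part were chosen after the result was seen.

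Immediate early genes were higher in RORgt_LTi, with Junb, a subunit of the AP-1 factor, at 2601 against 192 CPM. A small set of strongly responding cells did not account for it, since at 1500 UMIs a Junb UMI was found in 93.2% of LTi-like cells of RORgt_LTi (1206 of 1221 kept) and 34.2% of RORgt_high (1039 of 1075 kept), 2.73 times as many. Unthinned, the shares were 99.0% at a median of 7482 UMIs and 80.7% at 13138, against 14.2% in erythroid-like cells of RORgt_high at 4546.5 but 94.1% (16 of 17, or 68.75% thinned) in mast-like cells of RORgt_LTi at 9544, so Junb RNA in that library was not limited to LTi-like cells. A difference in cell types alone could not be settled, since the list median within LTi-like cells was 1.37 (1.27 to 1.43) but the libraries shared only 1.86% of that class by cluster. Handling that reached the whole library may have raised these genes, but the test cannot tell it from levels that belong to other cell types. In 30 mast-like or hepatoblast-like cells of RORgt_LTi the list's sum was 2.09 times (2.00 to 2.18) that in RORgt_high cells outside the LTi-like class. The ratio was 1.94 (1.84 to 2.04) in the 17 mast-like cells and 2.42 (2.26 to 2.60) in the 13 others. Those 13 held collagen RNA and no Alb. Of 22 genes, 15 were higher in the 30 cells and 2 were lower. By class, 9 were higher and 2 lower in the 17 mast-like cells, against 15 and 2 in the 13 others. The 2 lower genes of the 30 cells, Ier5 (0.2076) and Btg2 (0.4616), were higher in LTi-like cells (2.109 and 1.657). Some ratios differed widely from those in LTi-like cells, with Atf3 at 3.798 against 104.1 and Egr1 at 11.72 against 0.8994. Others were close, such as Junb at 8.238 against 8.711. These 30 cells were not of the cell types of RORgt_high, and a state that belongs to the c-kit gate stays open as untested.

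Hemoglobin and liver RNA was nearly missing from RORgt_LTi. Erythroid-like cells in RORgt_high alone did not account for this, since Hbb-bs, the adult beta globin, was 1893-fold (523.8 to 15640) higher in LTi-like cells of RORgt_high than in those of RORgt_LTi (5121 against 2 UMIs). Free RNA from a single source in RORgt_high could not be settled, since Hbb-bs made up 47.2% of the UMIs of 4 hemoglobin genes in LTi-like cells and 42.5% in erythroid-like cells, 1.11 times (1.09 to 1.13) where 0.9 to 1.1 had been set. The other classes lay nearer to the erythroid-like share. They were at 45.4% (dendritic-like), 45.1% (ILC1 or NK-like), 45.3% (unnamed), 42.5% (macrophage-like) and 39.5% (hepatoblast-like). Every class of RORgt_high held hemoglobin RNA, with the least in LTi-like cells (786.6 CPM for these 4 genes). Another preparation or source of the RORgt_LTi cells cannot be told apart from other causes, with the hemoglobin list at 0.375 CPM (4 UMIs) there and at 790.4 CPM in LTi-like cells of RORgt_high.

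Rorc was lower in RORgt_LTi, at a ratio of 0.585. Scaling did not account for it, since the ratio nearest 1 over the scalings was 0.631. A difference in cell types alone could not be settled, since the ratio within LTi-like cells was 0.637 (0.622 to 0.653) but the libraries filled different clusters of that class. Merged cells of high UMI count did not account for it, since among LTi-like cells under the median UMI count of their library (610 and 537 cells) it was 0.587 (0.563 to 0.612). Whether the gates differ in RORγt itself stays open as untested.

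Car2, carbonic anhydrase 2 of red cells and some progenitors, was lower in Rorc-rich cells of RORgt_high (0.0876) and higher in those of RORgt_LTi (1.71), and the difference was not tested. Hmmr, a mitotic spindle gene, was likewise lower in RORgt_high (0.535) and higher in RORgt_LTi (3.002). In barcodes that the filter removed, Rorc was at 2540 CPM (2484 to 2597) in RORgt_high, above the 1624 of kept cells, and at 679.7 CPM (523.5 to 868) in RORgt_LTi, below the 950.0 of kept cells.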

How the results depend on the processing

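Of 238 answers to the comparisons, 197 were the same and 41 moved, and the cause was not tested for any. Of 798 list medians 565 were the same, 225 moved and 8 reversed, and of 600 ratios of named genes 544 were the same and 56 moved. A list median counted as reversed only if its main percentile lay in either outer tail. Sign changes of other lists were counted as the same or moved. Median-of-ratios scaling, a shift of 0.185 in LTi-like cells, turned the sign of small negative medians there, such as that of LTi identity genes (-0.06). These turns are not among the 8. Leaving out erythroid, macrophage, hepatoblast and mast clusters or shallow clusters, removing the highest doublet scores, leaving out histone genes and counting deep unnamed clusters as LTi-like were chosen after the data were seen, and the rest before. No paired analysis was possible because each group had 1 library with no link between cells. All deposited barcodes gave no LTi-like value, since only clustered cells had a class. Between groups, the higher and lower counts of LTi identity genes, the higher counts of immediate early and lymphoid factor genes and the lower counts of chemokine genes never moved by more than 1.5 times. With median-of-ratios scaling the lower S-phase genes over all cells went from 23 to 13 and, in LTi-like cells, the higher MHC class II genes from 1 to 4, the higher ILC1 and NK genes from 3 to 5 and the lower lymphoid factors from 2 to 1.

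The all-cell Rorc ratio of 0.585 was 0.631 with median-of-ratios scaling, 0.559 as a mean over cells and 0.563 over all barcodes. In LTi-like cells the Rorc ratio of 0.637 was 0.725 with median-of-ratios scaling, 0.608 as a mean over cells and also at Leiden resolution 1.2, 0.621 at 0.4, 0.574 with each library clustered on its own and 0.588 with deep unnamed clusters counted in. The share of cells with a Rorc UMI was 91.7% in RORgt_high and 94.7% in RORgt_LTi at deposited depth.

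By the rule for reversed medians given above, list medians over all cells reversed when cells were thinned for ILC1 and NK genes (0.38), neutrophil and monocyte genes (0.85) and megakaryocyte genes (0.0021). In LTi-like cells hepatoblast genes reversed when thinned (0.75). ILC1 and NK genes reversed there at Leiden resolution 0.4 (-0.92) and with deep unnamed clusters (-0.31). S-phase genes did so at resolution 1.2 (0.12) and G2/M genes with deep unnamed clusters (-0.89). The medians of thinned cells may rest on fewer list members, so a change of direction cannot be told from a change of members. The 37 higher G2/M genes in LTi-like cells became 18 as a mean over cells, 11 when thinned, 22 with doublets kept, 11 at resolution 0.4, 22 without histone genes and 0 with deep unnamed clusters, where 41 were lower.

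The LTi-like share of RORgt_high, 29.3%, was 38.1% at resolution 0.4, 22.9% at 1.2, 27.1% with cell cycle genes kept, 26.0% clustered on its own, 36.8% with the strict cell filter, 32.0% with doublets kept, 32.1% without histone genes and 53.5% with deep unnamed clusters. For RORgt_LTi, 94.9%, it was 96.1% at resolution 0.4, 71.6% on its own, 96.4% with the strict filter, 96.0% with doublets kept and 96.1% with deep unnamed clusters. Of LTi genes, 0 were higher in Rorc-rich LTi-like cells of RORgt_high, and at deposited depth 16 in RORgt_high and 17 in RORgt_LTi. The cycling share of RORgt_high was 47.3% at 1 UMI, 14.9% at 4, 53.2% at deposited depth and 8.95% in LTi-like cells, and that of RORgt_LTi 24.3%, 8.12% and 27.7% in the same order up to deposited depth.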

Other observations

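The overlap tests in this part were written down before they were run, while the rule that counts opposite genes and the checks against dendritic-like and macrophage-like cells were added after the results were seen. When each library was clustered on its own, the larger LTi-like cluster with the most H2-Aa was taken as rich in MHC class II, the genes that present peptides to T cells (242 cells against 710 others in RORgt_high and 152 against 769 in RORgt_LTi). H2-Aa was at 2030 against 26.9 CPM in RORgt_high and at 3303 against 56.5 CPM in RORgt_LTi. Il22 was lower in these MHC class II-rich cells, at 0.238 in RORgt_high and 0.305 in RORgt_LTi, and so was Il17f (0.246 and 0.385). Cfp, which encodes properdin, was higher at 18.6 and 10.2, Bcl2a1b, a survival gene, at 17.3 and 7.09, Siglecg, an inhibitory receptor, at 8.41 and 6.65, and Isg15, an interferon-induced modifier, at 5.96 and 3.78. Outside the MHC class II list 127 genes were higher in both libraries where 21.2 would be shared by chance, 5.99 times as many, and 46 went opposite ways where 55.9 would, which is consistent with a shared set of genes in these cells. Of the 127, 104 were also higher in dendritic-like or macrophage-like cells of RORgt_high than in its LTi-like cells. Without such genes, which left 7709 of 8607, 23 were shared where 4.79 would be by chance, and 27 went opposite ways where 26.6 would. Of the macrophage genes, C1qb was at 8.02 in RORgt_high and 458 in RORgt_LTi, where all 71 UMIs were in 1 cell. Adgre1 was at 16.3, Cd68 at 5.98 and C1qc at 3.46 in RORgt_high. In RORgt_LTi the 53 UMIs of C1qa and the 45 of C1qc were each in 1 cell. C1qa in RORgt_high (0 against 12 UMIs) was not higher. In RORgt_LTi Cd68 (0 against 7, 0 to 4.48) and Adgre1 (1 against 1, 6.45, 0.0822 to 507) had too few UMIs to compare. With every cell that held a macrophage gene UMI left out (178 and 151 cells kept) 119 were shared where 19.9 would be, but dendritic-like RNA or merged cells were not excluded.

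Each library also held Cxcr3-rich cells, which were set against the LTi-like cells of the same clustering (296 against 952 in RORgt_high and 116 against 921 in RORgt_LTi). In the Cxcr3-rich cells Ifng, the cytokine of ILC1 and NK cells, was higher at 52.2 (25.8 to 123) and 11.8, Klrk1, the NKG2D receptor, at 116 and 5.50, and Cd3g, a T-cell receptor chain, at 3.56 and 4.13. Il22 was lower at 0.302 and 0.0867 and Ccr6 at 0.168 and 0.295, while Rorc was at 0.989 and 1.41. Klrd1 was higher in RORgt_high only (23.8, against 1.62, 0.948 to 2.63, in RORgt_LTi). Tbx21 was higher in RORgt_high (28.2) and had too few UMIs in RORgt_LTi to compare (1 against 1, 8.25, 0.105 to 648), and the RORgt_LTi group had no class name and scored highest on T-cell markers. Outside the ILC1 and NK list 66 genes were higher in both where 19.2 would be shared by chance, 3.44 times as many, but 201 went opposite ways where 62.6 would (3.21 times), so a shared set of genes cannot be told apart from genes that merely vary in both libraries.

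Aire, the regulator of self-antigen display in the thymus, was higher in RORgt_LTi at 8.15 against 0.445 CPM (18.3, 11.1 to 31.9). Areg, a repair growth factor, was higher at 63.2 against 4.77 CPM (13.2). The collagens Col1a1 (37.2, 21.4 to 69.9) and Col3a1 (46.2, 27.2 to 84.3) of stromal cells were higher in RORgt_LTi over all cells, with 121 of 130 and 172 of 173 UMIs in the 13 cells named hepatoblast-like. When RORgt_LTi was clustered on its own, a stromal-like cluster of 60 cells had both collagens among its top 10 genes. That cluster also had 15 LTi markers detected and an LTi score of 0.0243, so not all of its cells need be stromal. Xist was at 263 CPM in RORgt_LTi and 51.0 in RORgt_high, and Ddx3y at 88.8 and 45.5, so each library held RNA of female and of male embryos.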
